A study of Mus musculus with 6 samples.

How the data were processed

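Polyadenylated RNA from 6 sorted samples of brain-derived mouse endothelial cells was sequenced, 3 labelled Fli-1 knockout and 3 labelled wild-type. Libraries were made with either of 2 TruSeq kits, a non-stranded and a stranded version, per the labels' protocols, which do not say which sample had which kit. The deposited table held raw read counts per gene symbol, 24421 genes in 6 columns, not normalised by the authors. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.4, STAR 2.6.1d, Subread 1.6.4 with featureCounts, and the builds mm10 and GRCm38. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Overlapping or antisense genes and members of near-identical families, such as ribosomal proteins, are therefore uncertain. Mitochondrially encoded genes were not analysed here, since no row of the table carried their names.

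Totals ranged from 17550185 to 21385951 counts, and the 10 most abundant genes took 7.14% to 8.43% of them. No 2 libraries agreed within sampling noise: chi-square per degree of freedom between pairs of libraries lay between 5.44 and 40.7. Gene symbols were matched to GENCODE M21 on GRCm38, and 23376 (95.7%) matched.

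Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr were kept (12753), libraries were scaled by TMM (factors 0.983 to 1.02), and the groups were compared with the robust quasi-likelihood F test and Benjamini-Hochberg adjustment at a false discovery rate (FDR) of 0.05. CPM values use the TMM-scaled library sizes, except for blood cell markers in the tests on the source of the Fli1 reads, which use unscaled totals. Fold changes are the libraries labelled knockout over those labelled wild-type. An exact permutation test of 3 against 3 libraries could not go below a two-sided p of 0.1, so single genes were tested only in models fitted across all genes. This design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

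The groups share replicate numbers 1 to 3. Deviations from the group means correlated at 0.776, 0.857 and 0.652 between libraries with the same number and at -0.68 to 0.07 between libraries with different numbers. Centring each group on its own mean pushes the different-number values down when the same-number values are high. The different-number values are therefore not separate evidence. The numbers were taken to pair the libraries on this ground; the pairing comes from the data, and the labels do not state it. The paired test adds the number as a block. It lowered the biological coefficient of variation from 0.189 to 0.0383 and left 2 residual degrees of freedom in place of 4. Small paired p-values and their standard errors thus rest on a spread pooled across genes. An exact test of 3 pairs could not go below a two-sided p of 0.25. The comparison without the block remains the designed one, and paired values stand beside it because the calls differ.

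Each test was tested on simulated counts for 12657 genes, of which 200 were changed. The paired test recovered 83%, 86% and 98% of genes changed by log2 0.5, 1 and 2, and 8.38% of its calls were false. The unpaired test recovered 23%, 60% and 80% with 0 false calls. DESeq2 with the block recovered 64%, 74% and 90%, with 2.01% false calls. With the block, limma-voom recovered 82%, 86% and 98%, with 9.375% false calls. The simulated counts took their replicate-number effects and gene dispersions from the real libraries under the paired test. These rates therefore assume the pairing and cannot check it.

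Of 38 gene lists, 36 had at least 3 tested members. Members were counted at the FDR over all genes tested and over the list alone, and lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Camera called 4 lists higher and 2 lower without the block and 8 and 3 with it. With an estimated correlation it called 0 in either design, with smallest adjusted p values of 0.135 and 0.285. That setting also confines camera to the residual degrees of freedom, 4 without the block and 2 with it, so small p-values were hardly reachable. The cholesterol synthesis list had an estimated correlation of -0.0185 with the block, below the preset. Its camera adjusted p still went from 3.34e-05 to 0.285. A call lost under this setting is therefore not shown to come from correlation between genes. In the paired design, fry called 1 list by direction.

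Named genes were Fli1, up to 12 genes per direction with the largest changes among called genes whose groups did not overlap and whose higher mean was at least 10 CPM, and members of each list chosen by unadjusted p or, for cell type and quality lists, also by level. The second part gave only Igf1 without the block, so it was repeated on the paired test after the data were seen. Other genes are said to have been chosen after their values were seen. Alternatives covered scaling, filters, DESeq2 1.42.0, limma-voom, a minimum change of 1.5-fold, a stricter FDR, the replicate block, omission of ribosomal protein genes and omission of each library. Repeats of these on the paired test, offsets for GC content and gene length (12314 genes) and omission of each pair were added after the data were seen.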

Results

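RNA was sequenced from mouse endothelial cells, the cells that line blood vessels, which were derived from brain, grown in culture and isolated by fluorescence-activated sorting. The study compared cells labelled Fli-1 knockout with cells labelled wild-type after 6 days of co-culture with a vascular niche, counted from the induction of the deletion with 4-OHT (4-hydroxytamoxifen, which activates tamoxifen-dependent recombinases). Fli1 encodes a transcription factor of the ETS family that is expressed in endothelial and blood cells. Each group held 3 libraries, numbered 1 to 3. Total counts were 21385951, 18604769 and 17550185 in the libraries labelled knockout and 20898686, 20569853 and 19599670 in those labelled wild-type. The labels do not say whether the 3 libraries of a group came from separate cultures or animals. The p-values therefore rest only on these libraries, whose differences may be technical, and on a spread that the models share across genes.

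Fli1 (ENSMUSG00000016087, GRCm38 chromosome 9, 32422204 to 32542861, minus strand) went against the group labels. Its normalised count was 76.8, 111 and 77.4 CPM (counts scaled to a common library size) in the libraries labelled knockout and 45.3, 59.6 and 45.8 CPM in those labelled wild-type. The means were 88.2 ± 19.3 CPM and 50.2 ± 8.11 CPM (SD, n = 3 each), and Fli1 was higher in the library labelled knockout in 3 of 3 same-numbered pairs. The log2 fold change was 0.81 ± 0.18 (SE), with an adjusted p of 0.878 in the edgeR comparison of the groups. With the replicate number as a block, called the paired test from here on, it was 0.81 ± 0.051 (SE), with an adjusted p of 1.25e-15. The labels do not name the deleted part of the gene, and a count per gene includes reads from exons outside it. These counts therefore do not check whether a deletion took place. All directions given here are those of the libraries labelled knockout relative to the libraries labelled wild-type.

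**Figure D1:**
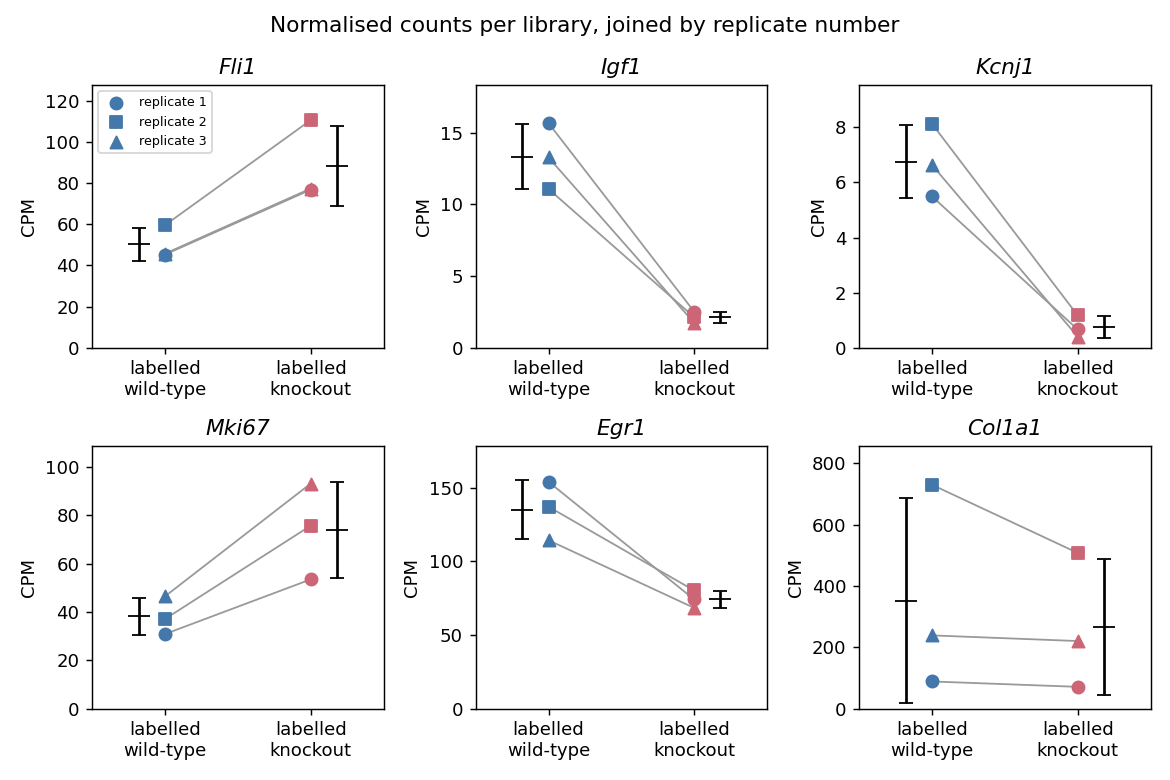
Normalised counts in CPM of 6 genes in each library; lines join libraries with the same replicate number, and the bars beside them show mean ± SD (n = 3). Fli1 lay between 76.8 and 111 CPM in the libraries labelled knockout and between 45.3 and 59.6 CPM in those labelled wild-type, whereas Igf1 and Kcnj1 were lower in all 3 libraries labelled knockout.

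The comparison asked which transcripts differ between endothelial cells labelled knockout and endothelial cells labelled wild-type. In the comparison of the groups without the block, edgeR called 0 genes higher and 1 gene lower among 12753 tested. That gene was Igf1, which encodes the secreted insulin-like growth factor 1 (GRCm38 chromosome 10, 87858265 to 87937042). It averaged 2.13 ± 0.39 CPM in the libraries labelled knockout and 13.3 ± 2.29 CPM in those labelled wild-type (SD, n = 3), a log2 fold change of -2.64 ± 0.20 (SE) with an adjusted p of 0.0383, and it was lower in 3 of 3 pairs. The next gene had an adjusted p of 0.395, and 611 genes had an unadjusted p under 0.05. The groups did not overlap for 10.2% of tested genes, against 10% expected by chance if all 6 libraries were exchangeable. Same-numbered libraries correlated, so that expectation does not hold here. The change had the same sign in all 3 pairs for 40.7% of tested genes, against 25% expected by chance. Neither share was tested. DESeq2 called 12 higher and 7 lower, and limma-voom called 0 in either direction. Leaving out any library other than wild-type replicate 2 ended the Igf1 call, at log2 fold changes from -2.50 to -2.78.

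The paired test called 613 genes higher and 511 lower, 8.81% of those tested, of which 54.5% were higher. With scaling by library size alone, 39.1% of the calls were higher. Of these calls, 169 higher and 95 lower genes changed by at least 1.5-fold, and 24 and 21 by at least 2-fold. Without pair 2, whose libraries had the most stromal transcripts, the counts were 339 and 205. DESeq2 with the same block called 262 and 111. Kcnj1, a potassium channel gene that lies next to Fli1 and was chosen after its values were seen, averaged 0.749 ± 0.39 CPM against 6.75 ± 1.32 CPM (SD, n = 3), and its log2 fold change was -3.15 ± 0.21 (SE, adjusted p = 8.18e-15). In the group comparison none of these genes passed other than Igf1, so every call below comes from the paired test unless stated otherwise.

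**Figure D2:**
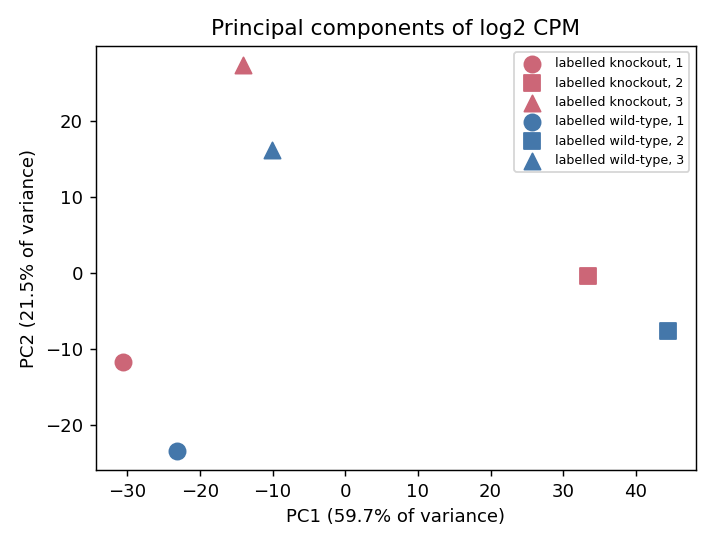
Scores of the 6 libraries on the first and second principal components of log2 CPM, which held 59.7% and 21.5% of the variance; colours give the group label and symbols the replicate number. Libraries with the same number lay next to each other, and the groups did not separate on the first component. They did on the third, which held 9.64% of the variance and is not drawn. Scores there were -13.2, -14.2 and -5.08 in the libraries labelled knockout and 8.97, 8.10 and 15.4 in those labelled wild-type.

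Genes of cell division were higher in the libraries labelled knockout. All 30 tested members of the G2/M list, genes that act in late cell cycle and mitosis, rose, with a median log2 fold change of 0.84 and medians of 0.82, 0.87 and 0.78 in the 3 pairs. Mki67, a marker of proliferating cells, averaged 74.0 ± 19.9 CPM against 38.1 ± 7.84 CPM (SD, n = 3), a log2 fold change of 0.95 ± 0.056 (SE, adjusted p = 1.2e-16). Hmmr rose by 0.94, Aurkb, a mitotic kinase, by 0.92 and Ndc80, a kinetochore protein, by 0.76 on the log2 scale. Cdc25c, a phosphatase that activates the mitotic kinase Cdk1, rose by 1.22 from a low level of 1.49 ± 0.41 to 3.48 ± 0.86 CPM (SD, n = 3). Kif18b, Dlgap5, Cep55 and Nuf2, which act in the spindle, kinetochore or cytokinesis, had log2 fold changes of 1.23, 1.18, 1.07 and 1.06. Of the 35 DNA replication genes tested, 28 rose and 0 fell, with a median of 0.48. Mcm10 rose by 1.03, the polymerase subunit Pole by 0.82, the ribonucleotide reductase subunit Rrm1 by 0.55 and the helicase subunit Mcm6 by 0.43.

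In the group comparison, 0 members of either list passed over all genes tested, and 26 of 30 G2/M genes and 0 of 35 replication genes passed when adjusted over the list alone. A camera set test with a preset correlation placed both lists higher, with adjusted p values of 1.26e-26 and 3e-19 without the block and 2.59e-37 and 1.48e-23 with it. These calls did not pass with an estimated correlation, which also leaves camera only the residual degrees of freedom. The adjusted p values were then 0.674 and 0.679 without the block, and 0.285 for both with it. The fry test gave adjusted p values of 0.0134 for the G2/M list and 0.0509 for the replication list in the paired design, and 0.562 and 0.585 without the block. Without pair 2, 30 and 25 members were higher.

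**Figure D3:**
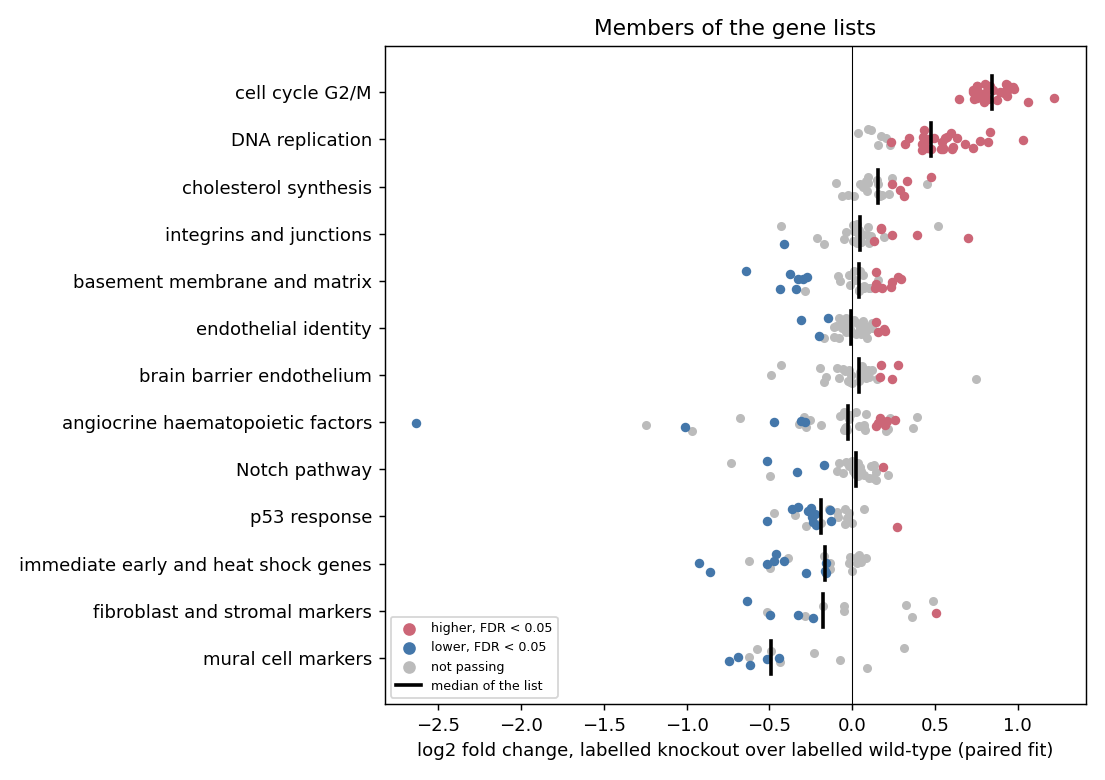
Log2 fold change in the paired test of every tested member of 13 gene lists, with genes called higher in red, called lower in blue and others in grey; the black bar marks the median of the list. The G2/M median was 0.84 and the DNA replication median 0.48, while the endothelial identity median was -0.01.

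In the p53 response list, 12 of 27 tested members fell, 1 rose and 14 did not pass, with a median log2 fold change of -0.19. Btg2, an antiproliferative gene, fell by 0.51, Polk, a translesion polymerase, by 0.33 and Mdm2, the ubiquitin ligase of p53, by 0.27 on the log2 scale, whereas Gadd45a rose by 0.27. The immediate early and heat shock list was written as a sign of RNA quality and cell handling, and it moved with the group: of 24 genes, 10 fell, 0 rose and 14 did not pass, with a median of -0.16. Egr1 averaged 74.2 ± 5.92 CPM against 135 ± 19.9 CPM (SD, n = 3), a log2 fold change of -0.86 ± 0.052 (SE, adjusted p = 9.48e-15). Fos fell by 0.93, Zfp36 by 0.47 and Dusp1 by 0.28. The 10 genes that fell are immediate early genes, and none is a heat shock gene. Both lists were lower by camera, with adjusted p values of 5.54e-06 and 2.86e-05 in the paired design, and adjusted p = 0.285 for each with an estimated correlation. Adjusted over the list alone without the block, 3 p53 genes and 4 immediate early genes were lower and 1 p53 gene was higher. Without pair 2, 8 and 7 members were lower.

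Endothelial identity genes showed small changes in both directions. Of 39 tested members, 4 rose and 3 fell. Emcn, a sialoglycoprotein of the endothelial surface, rose from 1118 ± 128 to 1278 ± 94.3 CPM (SD, n = 3), by 0.20 on the log2 scale, and Ptprb, a phosphatase that acts on vascular receptors, also rose by 0.20. Lmo2 and Sox7, transcriptional regulators of the endothelial lineage, fell by 0.31 and 0.20. Without pair 2, 0 members rose and 2 fell, and Sox7 no longer passed; with scaling by library size alone, 2 rose and 5 fell. Among 17 ETS factors, Fli1 rose and Ets2 fell by 0.24, from 199 ± 3.86 to 168 ± 6.80 CPM (SD, n = 3).

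Factors that endothelial cells supply to blood stem cells, written as a list of 43 genes, split between higher and lower: of 39 tested, 6 rose and 5 fell. Igf1 had the lowest log2 fold change of the list, -2.63 in the paired test with an adjusted p of 7.86e-18. Tgfb2 rose by 0.26, Bmp4 by 0.17 and Igfbp7 by 0.14. Kitl and Cxcl12, which encode stem cell factor and a chemokine that retains blood stem cells, were chosen after their values were seen and rose by 0.20 and 0.21. Igfbp5, also chosen afterwards, fell by 1.01, but its mean of 21.1 ± 31.5 CPM in the libraries labelled wild-type rested on replicate 2. Without pair 2, Bmp4, Igfbp7, Kitl, Cxcl12 and Igfbp5 no longer passed, and 2 members rose and 2 fell.

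Of 32 integrin and junction genes, 6 rose and 1 fell: Itga2, a collagen receptor subunit, rose from 17.1 ± 2.38 to 27.9 ± 4.59 CPM (SD, n = 3), by 0.70 on the log2 scale, and Itgav by 0.24. Camera placed this list higher in the paired design (adjusted p = 0.0344), and the adjusted p was 0.469 with an estimated correlation. Without pair 2, 4 members rose and 2 fell. Of 30 inflammatory genes, 6 rose and 2 fell. The leukocyte adhesion molecule Vcam1 rose by 0.28, while Ptgs2, the inducible cyclooxygenase, fell by 0.72, from 462 ± 125 to 286 ± 110 CPM (SD, n = 3). Of 32 basement membrane and matrix genes, 8 rose and 7 fell; without pair 2, 4 rose and 5 fell. Col18a1 rose by 0.30 and Thbs1 by 0.24, and the protease Adamts1 fell by 0.29.

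Transcripts of other cell types were also measured. Col1a1, a fibroblast collagen, differed more between replicate numbers than between the groups, at 71.0, 508 and 220 CPM in the libraries labelled knockout and 88.5, 730 and 239 CPM in those labelled wild-type. Of 13 mural cell markers, 0 rose and 5 fell, with a median log2 fold change of -0.49; the medians within the pairs were -0.59, -0.55 and 0.14, so pair 3 went the other way. Camera placed the mural list lower in the paired design (adjusted p = 0.0133), and the adjusted p was 0.755 with an estimated correlation. Of 13 fibroblast markers, 1 rose and 4 fell. Without pair 2, 2 members of each list fell and 0 rose. Of 24 haematopoietic markers, 10 were tested: 5 rose and 0 fell, including Srgn by 0.72 and Lcp1 by 0.20. Lcp1 no longer passed without pair 2. Ptprc, with 5 reads in the libraries labelled knockout and 11 in those labelled wild-type, was too low to be tested. Rac2 and Tyrobp had 0 reads in both groups. A difference in blood cell content cannot be read from the 5 rises alone. Without pair 2, 3 of 11 tested rose, and with scaling by library size alone 4 rose and 1 fell. Camera placed the list higher (adjusted p = 0.0254; adjusted p = 0.469 with an estimated correlation). Cd34 and Kit, listed there but abundant in both groups here, were not called, with means of 942 ± 84.8 against 1008 ± 98.5 CPM and 324 ± 37.0 against 343 ± 44.9 CPM (SD, n = 3).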

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

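The paired alternatives other than the block itself were chosen after seeing the data; those without the block were planned. Fli1 was higher and Igf1 lower under every alternative run. Without the block, Fli1 passed with DESeq2 (0.81, adjusted p = 0.0068) and with the replicate block (0.81), and with no other alternative. Igf1 no longer passed with limma-voom (-2.62), at a minimum of 1.5-fold (-2.64) or at an FDR of 0.01 (-2.64). Leaving out 1 library gave -2.50 to -2.78 for Igf1 and 0 to 1 genes lower. DESeq2 called 12 genes higher and 7 lower; limma-voom, the 1.5-fold minimum and the FDR of 0.01 called 0 lower, and the replicate block called 613 and 511. The cause was not tested.

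In the paired test, counts higher and lower were 262 and 111 with DESeq2, 22 and 5 at a minimum of 1.5-fold, and 388 and 259 at an FDR of 0.01. GC and length offsets gave 926 higher. Leaving out each pair in turn gave 339 to 603 higher and 205 to 600 lower; without pair 2, 501 of the 1124 genes were still called. DNA replication members higher numbered 18 with DESeq2. At a minimum of 1.5-fold, 9 G2/M and 0 replication genes were higher, and 0 p53 genes and 2 immediate early genes lower. Of 53 single genes named as passing the paired test, besides Fli1 and Igf1, 44 no longer passed at a minimum of 1.5-fold, 10 without pair 2, 4 with DESeq2, 2 with library size alone and 2 at an FDR of 0.01. Of the lists, camera called 8 higher with the replicate block. Without the block, an estimated correlation or fry gave 0 higher and 0 lower, and leaving out 1 library gave 4 to 10 lists higher; with the block, fry called 1 list.

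Without the block, leaving out 1 library turned the direction of Col1a1 (-1.27 to 0.70), Kitl (-0.010 to 0.33), Igfbp5 (-3.74 to 1.80), Ets1 (-0.057 to 0.042), Arhgap32 (-0.056 to 0.10) and Coro1a (-0.039 to 0.68), of which none passed. In the paired test, leaving out a pair turned Ets1 (-0.022 to 0.013) and Arhgap32 (-0.019 to 0.10). The block changed the calls of the single genes given as rising or falling, other than Igf1, from not passing to passing.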

Other observations

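Of 24 tested cholesterol synthesis genes, 5 rose in the paired test, 0 fell and 19 did not pass, with a median log2 fold change of 0.16. Srebf2, the transcription factor that activates the pathway, rose from 72.2 ± 2.62 to 89.5 ± 1.42 CPM (SD, n = 3), by 0.31, and Insig1 by 0.33. Camera placed the list higher without the block (adjusted p = 1.79e-05), and with an estimated correlation the values were adjusted p = 0.674 without the block and 0.285 with it. Of 35 ribosomal protein genes, also written as a list of RNA quality, 8 rose, with a median of 0.08; without pair 1 only 1 rose and without pair 2 only 2. Their camera call (adjusted p = 3.34e-05, paired) was also lost, at adjusted p = 0.848 with an estimated correlation. The long nuclear RNA Malat1 fell by 0.51, from 474 ± 117 to 329 ± 45.4 CPM (SD, n = 3), and Neat1, another nuclear RNA chosen after its values were seen, by 0.47.

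In the interferon response list 3 of 36 members rose, and 2 without pair 2. Of 29 stress response genes 5 rose and 1 fell; the counts were 2 and 2 with scaling by library size alone, 3 and 0 without pair 2, and 2 and 0 without pair 3. Camera called both lists higher in the paired design (adjusted p = 0.00553 and 0.036), and the values were adjusted p = 0.377 and 0.609 with an estimated correlation. Of 29 VEGF, TGF-β and BMP signalling genes, 0 rose and 4 fell, among them Tgfbr3 by 0.34; without pair 2, 2 fell. Of 28 Notch pathway genes, 1 rose and 3 fell, with Hes1, a Notch target, falling by 0.33; without pair 2, 0 rose and 3 fell. Of 30 brain barrier genes 4 rose and 0 fell, with the efflux transporter Abcg2 rising by 0.24; without pair 2, 2 rose and 2 fell.

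Tests on the source of the Fli1 reads from blood cells and from undeleted parts of the gene, on stromal cells for Igf1, the windows around Fli1 other than 5 Mb and the GC and length offsets were chosen after the results were seen.

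Fli1 was higher in the libraries labelled knockout by 38.0 CPM, and differences in scaling do not account for this, since its lowest paired log2 fold change over 4 scalings was 0.78. For blood cells in the sorted fraction a first test decided nothing: the median level of Ptprc, Cd53, Laptm5, Coro1a and Vav1 was 7.05 CPM in those libraries, between 0.1 of the excess and the excess, with Laptm5 and Coro1a called higher, Cd53 (7.1 against 8.5 CPM) not called, and Ptprc (0.078 against 0.178 CPM, from 5 and 11 reads) too low to be tested. A later test, chosen after those values and many others on the list were seen, took the difference between the groups over all 24 haematopoietic markers. Its median was 0 CPM (median absolute deviation 0.119), and 20 markers rose by under 0.1 of the excess, fell or did not change. Laptm5, Lcp1, Arhgdib and Srgn rose by 31.6, 40.6, 25.6 and 14.2 CPM. Leukocytes would raise most of these markers, so the values argue against them as the source. The test was chosen too late to exclude them. Marker levels in this paragraph, unlike the Fli1 excess, are CPM of unscaled library totals. Megakaryocytes, which that list does not cover, stay open, with Pf4 at 0.565 against 0.503 CPM. Reads from exons outside the deletion and exchanged group labels cannot be told apart, because no count over the deleted exons was used here and the gene count gives only the log2 fold change of 0.81; a biological rise of Fli1 transcription also stays open and was not tested.

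Kcnj1, a potassium channel gene 23007 bp from Fli1 that was chosen after its values were seen, fell from 6.75 ± 1.32 to 0.749 ± 0.39 CPM (SD, n = 3), with a paired log2 fold change of -3.15 ± 0.21 (SE, adjusted p = 8.18e-15) and an adjusted p of 0.395 without the block; it was lower in 3 of 3 pairs. A candidate explanation is a chromosome segment around Fli1 that differs between the groups: 7 of 34 other tested genes within 5 Mb (20.6%) were called, against 8.80% elsewhere (one-sided Fisher's exact test, p = 0.0266). Other windows did not all show this: 0 of 2 genes were called within 1 Mb, 1 of 9 within 2 Mb (p = 0.565), 11 of 64 within 10 Mb (p = 0.0233) and 24 of 220 within 20 Mb (p = 0.163), all by the same exact test and unadjusted for the 5 windows. The nearest tested genes apart from Kcnj1 were not called, Ets1 at -0.00 and Arhgap32 at 0.03, and the nearest called gene was Kirrel3 at 1943033 bp. The other called genes within 5 Mb lay 4165621 to 4859036 bp away, near the edge of the window. They changed in both directions, with log2 fold changes from -0.79 to 1.14. An effect of the deletion itself on Kcnj1 stays open and was not tested.

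The rise of cell cycle genes was tested against 3 technical explanations. With GC and length offsets 30 of 30 G2/M genes were still higher, with a median of 0.84. In the pairs whose library labelled knockout was the smaller one, the list median was at least 0.78, so depth does not account for it. The slope of G2/M levels on stromal markers predicted -3.21% of the rise. A difference in proliferation between the groups may underlie it, a hypothesis that was not tested here and that a count of dividing cells would decide; with Fli1 against its label, which group it would concern is uncertain.

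Fewer stromal cells could lower Igf1. Fibroblast and mural markers had a median paired log2 fold change of -0.31 (median absolute deviation 0.38), against -2.63 for Igf1. These values argue against a loss of fibroblast or mural cells as the whole source of the Igf1 fall. In the comparison without the block, the smallest Igf1 log2 fold change over 4 scalings was -2.63.

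Splits of the 6 libraries were too few for a share under 0.05. The real groups called 1 gene without the block, as did 1 of the 10 splits, the real one, and the highest other split called 0. Among the 4 splits that part all 3 pairs, the real one called 1124 genes in the paired test and the highest other 0; the other 3 exchange the labels of 1 pair. The 5 other ways of matching the numbers between the groups each called 0 genes.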
